A study of Rattus norvegicus with 15 samples.

How the data were processed

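Total RNA was purified from mesenteric arteries with a kit for fibrous tissue, and biotin-labelled cRNA was made from small RNA amounts, per the labels' protocols. The deposited signal values, never negative and 1 per probe set and array, were made by the authors with GCOS and the MAS5 method, per the submitters' processing notes; versions are not given in the sources used here. The deposited signals had been scaled, since the mean after trimming 2% was between 1001.1 and 1001.7 on every array over the probe sets used. Such scaling makes arrays comparable only if total RNA is alike, and it raises dim probe sets and spike-ins on an array with little labelled sample RNA. Background subtraction and detection calls were not used here. The table held 8799 probe sets on 15 arrays in 4 groups, taken from the sample titles.

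Signals were set to a floor of 1 (12 values lay below it) and taken to log2. The 59 array control probe sets were left out of the tests. A probe set was tested if its signal was at or above its own array's 40th percentile on at least 3 arrays, which left 6512. Gene names came from the platform annotation. Of its symbols, 6985 were matched to a gene table by gene identifier and 0 differed from it. Of 8740 probe sets, 7006 had 1 gene symbol, 308 had several and 1426 had none in that annotation, and a probe set with several or none was left unnamed. No genome was used, so no positions are given.

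Differences were tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups over all 15 arrays, a moderated two-sided test with a trend of the variance on mean signal (11 residual and 7.19 prior degrees of freedom) and Benjamini-Hochberg adjustment over the tested probe sets, at 0.05. The 6 comparisons were collateral against control arteries in each strain, the difference and the mean of these, and SHR against WKY in each vessel type. Before the data were examined, 40 gene lists for pathways and cell types were fixed, and 39 had at least 5 tested genes. Lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene (the highest mean signal, 3825 genes) and adjustment over lists, beside camera with an estimated correlation and fry. Camera compares a list with other genes. Fry asks whether its genes move 1 way on balance, and its mixed form whether they change in either direction.

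Genes were named by a rule fixed before the data were examined. It took up to 10 genes per direction that passed with no overlap between groups, up to 4 members with the smallest p of each list that passed or had a passing member, the 5 genes with the smallest p per direction where fewer than 10 passed, and 18 fixed genes where measured. The text gives part of these. The examples given for the probe sets at an unadjusted p under 0.05 in both strains were chosen after their values were seen.

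The fits were tested on simulated data made from the real arrays' means and spread. For the strain difference in control arteries, 8.06% of probe sets with a log2 change of 1, 48.4% with 2 and 76.7% with 3 were recovered. For WKY collateral against control arteries the shares were 11.9%, 44.8% and 77.6%. A list shifted by -1 was called in 5 of 5 runs of each. The simulated genes varied independently of each other, so these runs do not show how list calls behave where genes are correlated. For arrays the precision is set by their number and by signal over background.

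Alternatives planned in advance were quantile normalization, equal array medians, a constant added before log2, no filter, a 60th percentile filter, no variance trend, array weights, only the arrays of the groups compared, the replicate number as a fixed or random block, each array left out, Welch's test, thresholds of 0.10 or 0.05 with 1.5-fold, an estimated correlation, fry, and the mean over a gene's probe sets. Exact permutation of list means, covariates for spike-in signal and 3' to 5' ratio, array weights without SHR collateral 3, and permutation of 2 list means without that array were added after seeing the data, as was the comparison of named genes with each array's 20th percentile.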

Results

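Gene expression was measured in rat mesenteric arteries, the small arteries that supply the gut, on 15 Affymetrix rat arrays. The arteries came from the spontaneously hypertensive rat (SHR), an inbred strain that develops high blood pressure, and from the Wistar Kyoto rat (WKY), its usual normotensive comparison strain. Each strain gave control arteries and collateral arteries, which carry added flow after adjacent arteries are occluded. There were 4 SHR control, 4 SHR collateral, 3 WKY control and 4 WKY collateral arrays. The series asks about the molecular basis of poorer collateral growth in SHR, so the comparisons were collateral against control arteries within each strain, the difference between those changes, their mean, and SHR against WKY within each vessel type. Of 8740 probe sets that are not array controls, 6512 passed the filter on low signal and were tested. The labels do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples. The number of arrays limits the precision: the median standard error was 0.54 on the log2 scale for WKY collateral against control arteries and 0.50 for SHR.

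The array SHR collateral 3 stood apart from the other 14. Its Spearman correlation with them over the tested probe sets lay between 0.496 and 0.657, while the other 14 correlated with each other between 0.805 and 0.931. The mean signal of its 9 spike-in control probe sets, which report RNA added in fixed amounts, was 172400, against 10427 to 56516 on the other arrays. Its 20th percentile of signal was 171.2, against 43.4 to 83.3. The mean log2 ratio of 3' to 5' signal of actin and Gapdh, a sign of RNA quality, was 1.86 on this array, and the strains differed in it, with SHR lower by a mean log2 difference of -0.38 (95% interval -0.65 to -0.12).

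**Figure D1:**
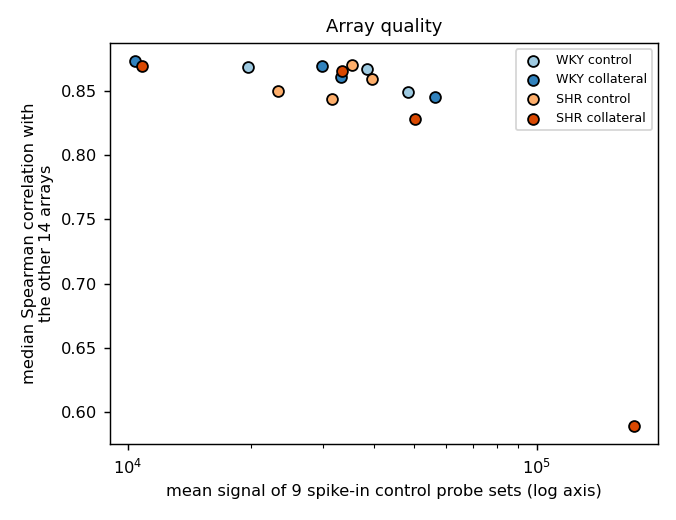
Each point is 1 of the 15 arrays, coloured by group, with the mean signal of 9 spike-in control probe sets on the horizontal log axis and the median Spearman correlation with the other 14 arrays on the vertical axis. SHR collateral 3 lies alone at a signal of 172400 and a median correlation of 0.590.

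In WKY, the genes of cholesterol synthesis were shifted upward in collateral against control arteries, with a median log2 change of 0.46 over 15 measured members (camera, adjusted p = 0.00102). The call did not hold with an estimated correlation between genes (adjusted p = 0.221). Of the 15 members, 12 had a change above 0, 5 had an unadjusted p under 0.05 and 1 passed when adjusted over the list alone, but 0 passed over all probe sets. Examples were Idi1 at 1.14 ± 0.32 (SE, 4 against 3 arrays), Fdps at 1.16 ± 0.39, Mvd at 1.60 ± 0.62 and Cyp51 at 1.16 ± 0.50, all enzymes of the sterol pathway. Immediate early genes, which code for quickly induced transcription factors and regulators, were shifted downward with a median of -0.59 over 24 members (adjusted p = 0.00102), also without a call under an estimated correlation (adjusted p = 0.718) and without WKY control 1 (adjusted p = 0.3003). Jun stood at -1.82 ± 0.70, Nr4a1 at -1.29 ± 0.64 and Fos at -0.91 ± 0.45, while Fosl1 went the other way at 1.51 ± 0.60.

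The WKY genes with the smallest p in the upward direction were Esm1, an endothelial proteoglycan, at 1.99 ± 0.42, Plaur, the urokinase receptor, at 1.83 ± 0.43, Idi1, the amino acid transporter Slc7a1 at 1.64 ± 0.46 and the metalloproteinase inhibitor Timp1 at 0.87 ± 0.26. In the downward direction they were the protease inhibitor Cst3 at -1.12 ± 0.31, the detoxification genes Sult1a1 at -1.60 ± 0.47, Gstt2 at -1.61 ± 0.50 and Ephx1 at -1.56 ± 0.49, and the cytochrome P450 Cyp2j3 at -1.64 ± 0.56. All had an adjusted p of 0.99988. With limma, 0 of 6512 probe sets passed an adjusted p of 0.05 (smallest 0.99988), and 206 had an unadjusted p under 0.05, against 325.6 expected by chance. The same comparison without a moderated variance also gave 0 after adjustment. Among genes fixed in advance, the chemokine Ccl2 stood at 0.95 ± 0.46, the angiotensin receptor Agtr1a at -1.21 ± 0.59, the nitric oxide synthase Nos3 at -0.51 ± 0.60 and smooth muscle actin Acta2 at 0.09 ± 0.39, none past the threshold.

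In SHR, 10 of 39 gene lists were shifted in collateral against control arteries, 9 of them downward. Fibroblast markers had a median log2 change of -0.45 over 11 members (camera, adjusted p = 0.00435, and 0.671 with an estimated correlation), with Thy1 at -1.78 ± 0.57 (SE, 4 against 4 arrays), Igfbp6 at -0.68 ± 0.29 and the matrix proteoglycan Dcn at -0.61 ± 0.29. Acute phase and complement genes had a median of -0.35 over 16 members (adjusted p = 0.0347, and 0.793 with an estimated correlation), with Lbp, which binds bacterial lipopolysaccharide, at -1.20 ± 0.42. With quantile normalization 0 lists were called (adjusted p = 0.186 for fibroblast markers and 0.296 for complement), and array weights kept 2, fibroblast markers and immediate early genes. Leaving out SHR collateral 3 kept 2 of the 10 calls, fibroblast markers and complement, with 1 new one. Without SHR control 2 there were 4 calls, without SHR control 1 or 3 or SHR collateral 4 there were 5, and without SHR collateral 1 or 2 there were 6. The fibroblast call was lost without SHR collateral 4 (adjusted p = 0.0563), and the complement call without SHR control 1, 2 or 3 or SHR collateral 2 or 4 (largest adjusted p = 0.344). The 8 calls lost without SHR collateral 3 were downward for oxidative phosphorylation (median -0.23), immediate early genes (-0.30), fatty acid oxidation (-0.32), contractile smooth muscle genes (-0.29), antioxidant genes (-0.24), extracellular matrix proteins (-0.17) and cytosolic ribosomal proteins (-0.18), and upward for lymphocyte markers (0.71). With an estimated correlation their adjusted p lay between 0.765 and 0.910. The ribosomal list turned upward in the camera test after quantile normalization, and the contractile median was 0.07 without SHR collateral 3. Of the lymphocyte markers, Cd79b stood at 1.62 ± 0.71, and of the contractile genes Itga7 stood at -0.98 ± 0.28 and Kcnma1 at 1.73 ± 0.61. Of these 8 calls, oxidative phosphorylation was lost without SHR collateral 3 alone (adjusted p = 0.607), and each of the others also without at least 2 other arrays. Ndufs8 of the respiratory chain stood at -0.98 ± 0.36.

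In SHR too, limma called 0 probe sets at an adjusted p of 0.05 (smallest 0.949), as did the comparison without a moderated variance. An unadjusted p under 0.05 was reached by 245, against 325.6 by chance. The smallest p values upward belonged to genes such as Nup155, of the nuclear pore, at 2.29 ± 0.64 and the receptor tyrosine kinase Erbb2 at 1.58 ± 0.48. Downward they belonged to genes such as Smarcd2, of a chromatin remodelling complex, at -1.57 ± 0.42 and the clock-controlled transcription factor Dbp at -2.76 ± 0.82. Ccl2 stood at 0.94 ± 0.43, Agtr1a at -1.05 ± 0.55, the mitochondrial antioxidant enzyme Sod2 at 0.80 ± 0.39, smooth muscle myosin Myh11 at -0.74 ± 0.55, Nos3 at -0.15 ± 0.55 and Timp1 at -0.02 ± 0.24.

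The difference between the strains' collateral changes was tested directly. For cholesterol synthesis genes the median log2 difference, SHR change minus WKY change, was -0.69 over 15 members, 12 of them below 0 (camera, adjusted p = 0.00446). The call was lost with an estimated correlation (adjusted p = 0.410), with a 60th percentile filter (adjusted p = 0.156) and with array weights (adjusted p = 0.206), and without SHR collateral 3 the median was -0.50 (adjusted p = 0.0335). In SHR alone the list was not called (adjusted p = 0.851), with a median of 0.10 and a mean of -0.13. Dhcr7, which completes cholesterol synthesis, had the smallest p of the list at -1.26 ± 0.58 (SE). Cytosolic ribosomal proteins had a median difference of -0.24 over 37 members (adjusted p = 0.00446). That call was lost with an estimated correlation (adjusted p = 0.880), without SHR collateral 3 (adjusted p = 0.473) and without WKY collateral 4 (adjusted p = 0.0974). It was also lost with quantile normalization (median -0.056, adjusted p = 0.706), array weights (adjusted p = 0.206) and the replicate number as a fixed block (adjusted p = 0.132). With limma, 0 probe sets passed for the difference (smallest adjusted p = 0.99969), and 124 had an unadjusted p under 0.05, against 325.6 by chance. Tgfb3, a growth factor, stood at -1.92 ± 0.64, the actin crosslinker Flnc at -1.45 ± 0.49 (-2.25 by its other probe set) and Timp1 at -0.89 ± 0.36. Ccl2 had a difference of -0.01 ± 0.63 and Nos3 one of 0.36 ± 0.82.

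Across the 6512 probe sets the changes in the strains had a Pearson correlation of 0.115 and a Spearman correlation of 0.110, and the Pearson value ranged from 0.0293 without WKY control 1 to 0.178 without SHR collateral 3. Genes are not independent replicates, and the 2 contrasts share no arrays. An unadjusted p under 0.05 in both strains was found for 17 probe sets, of which 6 were higher in both (2.36 expected for independent lists) and 10 lower in both (1.55 expected). These included Esm1 (1.99 in WKY and 0.85 in SHR), Dlk1 (1.03 and 1.18) and Crem (1.19 and 1.18) upward, and Cst3 (-1.12 and -0.80), Gstt2 (-1.61 and -1.14) and the matrix protein Fmod (-1.44 and -1.19) downward. The other probe set of Flnc stood at 1.25 in WKY and at -1.003 in SHR.

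In the mean of both strains, 6 lists were shifted downward in collaterals. Immediate early genes had a median log2 change of -0.42 over 24 members, 22 below 0 (camera, adjusted p = 0.000154, and 0.371 with an estimated correlation), and fibroblast markers one of -0.39 over 11 members, 10 below 0 (adjusted p = 0.00132, and 0.371 with an estimated correlation). Acute phase and complement genes (-0.45), oxidative phosphorylation (-0.16), antioxidant genes (-0.18) and fatty acid oxidation (-0.23) were the others, each with an adjusted p of 0.371 with an estimated correlation. The antioxidant and fatty acid calls were each lost without SHR control 1 or 3, SHR collateral 2 or 3 or WKY control 1 (largest adjusted p = 0.220 and 0.154), the first also without WKY collateral 3 and the second without WKY collateral 4. The complement call was lost without SHR collateral 2 (adjusted p = 0.0504). Quantile normalization gave 1 list upward and 2 downward, with a fibroblast median of -0.17 (adjusted p = 0.0518). Array weights gave 3 downward and 3 upward, namely the unfolded protein response (median 0.24), cell cycle (0.40) and cholesterol synthesis (0.30). Exact permutation of vessel labels within strain, two-sided, gave a smallest adjusted p of 0.284 over the 39 lists. That permutation did not pair arrays by replicate number, so it could miss a change if the numbers do pair samples. Esm1 stood at 1.42 ± 0.29 (SE), Plaur at 1.25 ± 0.30, Cst3 at -0.96 ± 0.21 and Gstt2 at -1.38 ± 0.34, each with an adjusted p of 0.652. With limma 0 probe sets passed, and 333 had an unadjusted p under 0.05, against 325.6 by chance.

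In control arteries, Icam2 and Ptprj were lower in SHR than in WKY. Icam2 (probe set rc_AI639370_at), an adhesion molecule of endothelial cells, had a log2 difference of -3.62 ± 0.61 (SE), with a mean log2 signal of 7.50 ± 1.26 (SD, n = 4) in SHR and 11.12 ± 0.29 (SD, n = 3) in WKY. Ptprj (U40790_at), a receptor tyrosine phosphatase, had a difference of -3.48 ± 0.58, with means of 6.22 ± 0.42 and 9.71 ± 0.74. Ptprj lay below the array's own 20th percentile of signal on 3 of 4 SHR control arrays, so the size of its difference is uncertain. With a constant of 68.5 added before log2 the differences were -2.66 for Ptprj and -3.11 for Icam2 (both adjusted p = 0.0186), and without SHR control 4 Icam2 stood at -3.03. For both, the adjusted p from limma was 0.0434 and the values of the strains did not overlap. Lack of overlap was common in this comparison, at 8.57% of all tested probe sets, against 5.71% by chance. Each has 1 tested probe set, so a strain difference in the probed sequence would give the same reading as a difference in level. These were the only calls among 6512 probe sets (0 higher, 2 lower), while 421 had an unadjusted p under 0.05, against 325.6 by chance, and the comparison without a moderated variance gave 0 after adjustment. Both calls were lost without any 1 of the WKY control arrays, with adjusted p up to 0.337, and in all Icam2 lost its call in 10 and Ptprj in 11 of the 15 fits that left out an array. There were 0 calls without SHR control 1 or 2, SHR collateral 2, any WKY control array or WKY collateral 1, 2 or 3, and 1 without SHR collateral 1 or WKY collateral 4. There were 6 without SHR control 4.

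**Figure D2:**
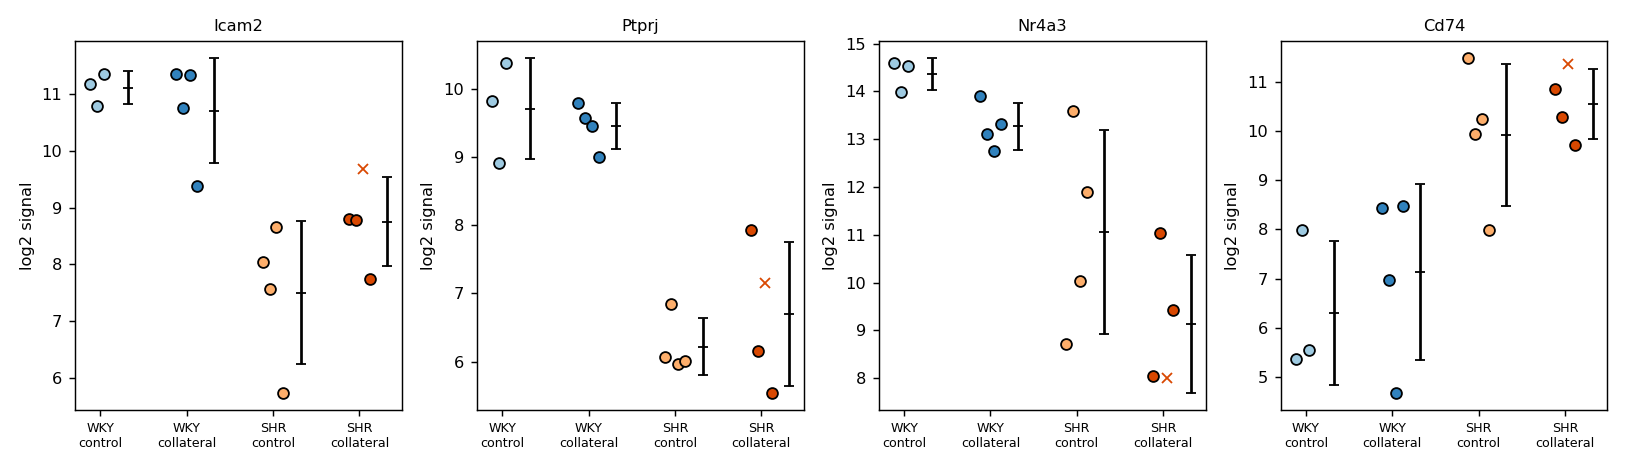
Log2 signal of Icam2, Ptprj, Nr4a3 and Cd74 on each array by group, with the mean and SD of each group at its right. The cross marks SHR collateral 3. Icam2 averaged 7.50 in SHR and 11.12 in WKY control arteries, with no overlap between the strains there, while in collaterals SHR collateral 3 at 9.69 lay above WKY collateral 4 at 9.39.

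Immediate early genes were shifted downward in SHR control arteries, with a median log2 difference of -1.16 over 24 members, 21 of them below 0 (camera, adjusted p = 8.78e-15). With an estimated correlation the adjusted p was 0.139. At an unadjusted p under 0.05 there were 13 lower members, 10 passed when adjusted over the list alone and 0 over all probe sets. Dusp1, a phosphatase of MAP kinases, stood at -1.99 ± 0.41, the transcription factors Klf6 and Egr2 at -2.45 ± 0.52 and -1.89 ± 0.42, and Fos at -1.31 ± 0.45. Endothelial markers also had a negative median of -0.49 over 12 members (adjusted p = 0.0199, and 0.594 with an estimated correlation), lost without SHR control 2, SHR control 4 or WKY control 1 (adjusted p = 0.0735, 0.0980 and 0.167). Their members went both ways, and with the mean of each gene's probe sets the median was 0.01 (adjusted p = 0.218). Besides Icam2, Selp stood at -1.45 ± 0.61 and Edn1 at -1.48 ± 0.67, while Pecam1 stood at 0.73 ± 0.44.

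Monocyte and macrophage markers were shifted upward in SHR control arteries, with a median of 0.79 over 10 members (adjusted p = 1.58e-05, and 0.279 with an estimated correlation). MHC genes were shifted upward with a median of 0.27 over 15 members (adjusted p = 0.00143, and 0.279 with an estimated correlation). Cd74, the invariant chain of MHC class II and a member of both lists, stood at 3.62 ± 0.90 (2.74 with the constant added, as 2 of 3 WKY control arrays lay below their 20th percentile), the class II chain RT1-Da at 3.62 ± 0.72, lysozyme Lyz2 at 2.15 ± 0.69 and the complement chain C1qb at 2.12 ± 0.68. After adjustment over the list alone, 3 macrophage and 5 MHC members were higher, and 0 passed over all probe sets. RT1 genes have near-identical copies that one probe set can read together, so their values are uncertain. Fibroblast markers (median 0.44), cell cycle genes (0.44) and cytosolic ribosomal proteins (0.20) were shifted upward too, with adjusted p of 0.0181, 0.0184 and 0.0184, and of 0.398, 0.398 and 0.835 with an estimated correlation. The fibroblast call was lost without SHR control 2 or 3 (adjusted p = 0.131 and 0.0724), and the cell cycle call without SHR control 1 or WKY control 3 (0.0940 and 0.167). The ribosomal call was lost without SHR control 1 or 2 or WKY control 1 or 3 (largest adjusted p = 0.0927). Cdk1, which drives mitosis, stood at 2.09 ± 0.87 and Igfbp6 at 0.92 ± 0.32.

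Other genes with a small p in control arteries, none past the threshold, were the ectonucleotidase Entpd2 at 1.43 ± 0.30, the protease inhibitor Cstb at 0.91 ± 0.21, the hyaluronan receptor Lyve1 at 1.62 ± 0.39 and the transcription factor Irf1 at -2.03 ± 0.43. Among genes fixed in advance, heme oxygenase Hmox1 stood at 1.87 ± 0.46 (adjusted p = 0.176), the oxidase subunit Cyba at 1.70 ± 0.59, the adhesion molecules Vcam1 and Icam1 at -2.72 ± 0.67 and -1.69 ± 0.45, Nos3 at -0.67 ± 0.60 and Acta2 at 0.05 ± 0.39.

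In collateral arteries, immediate early genes were again shifted downward in SHR, with a median log2 difference of -1.10 over 24 members, 21 below 0 (camera, adjusted p = 6.50e-12). With an estimated correlation the adjusted p was 0.244. There were 12 lower members at an unadjusted p under 0.05, 8 when adjusted over the list alone and 0 over all probe sets. Nr4a3, a nuclear receptor, stood at -4.14 ± 0.78 (SE, 4 against 4 arrays), Klf6 at -2.06 ± 0.48, Dusp1 at -1.52 ± 0.38 and Fosl1 at -2.06 ± 0.55. The list of adhesion molecules and the NF-kB pathway had a median of -0.43 over 14 members (adjusted p = 0.0156, and 0.385 with an estimated correlation), lost without SHR collateral 1, SHR collateral 4 or WKY collateral 1 (adjusted p = 0.0526, 0.0896 and 0.103). Its members included Nfkb1 at -1.49 ± 0.38, Ptgs2, the inducible cyclooxygenase, at -2.27 ± 0.67 and Vcam1 at -2.07 ± 0.62. Contractile smooth muscle genes (-0.70, with Des at -1.05 ± 0.43) and cholesterol synthesis genes (-0.57) were shifted downward with adjusted p of 7.14e-05 and 0.0266, and of 0.766 and 0.385 with an estimated correlation. Both calls were lost without SHR collateral 3, where the medians were -0.23 and -0.26 (adjusted p = 0.0797 and 0.0877), and the cholesterol call also without SHR collateral 2 or WKY collateral 3 (adjusted p = 0.106 and 0.0585).

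Monocyte and macrophage markers were shifted upward in SHR collaterals, with a median of 1.23 and all 10 members above 0 (adjusted p = 1.89e-06, and 0.244 with an estimated correlation). MHC genes had a median of 0.42 over 15 members (adjusted p = 0.0139, 0.385 with an estimated correlation, and 0.0526 without SHR collateral 1). Cd74 stood at 3.42 ± 0.83, C1qb at 2.30 ± 0.63 and the class I gene RT1-A3 at 3.24 ± 0.58, and 6 macrophage and 4 MHC members were higher when adjusted over the list alone. RT1-A3 and Cpa3 lay below the 20th percentile on 3 of 4 WKY collateral arrays, and with the constant added their differences were 2.09 and 1.64. With limma 0 probe sets passed an adjusted p of 0.05 (smallest 0.0783), the comparison without a moderated variance gave 0, and 496 had an unadjusted p under 0.05, against 325.6 by chance. At an adjusted p of 0.10 there were 6, namely RT1-A3, Nr4a3, Ptprj at -2.75 ± 0.53, the thrombin receptor F2r at -2.02 ± 0.34 and 2 probe sets left unnamed here. Ptprj lay below the array's own 20th percentile on SHR collateral 2 and SHR collateral 3, so the size of its difference is uncertain here too. There were 7 calls without SHR collateral 4, 4 without SHR collateral 2 and 2 without WKY collateral 1. Leaving out SHR control 1 or 2 gave 1, and any other array 0. Array weights gave 26, with the largest weight, 2.78, on SHR collateral 1. Icam2 stood at -1.96 ± 0.57 (adjusted p = 0.370) and its values in the strains overlapped. Hmox1 stood at 1.69 ± 0.43, Lyve1 at 1.46 ± 0.36, Cpa3, a mast cell protease, at 2.51 ± 0.64, Tgfb3 at -2.06 ± 0.44, Spp1 at -0.92 ± 0.58 and fibronectin Fn1 at -0.67 ± 0.30.

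**Figure D3:**
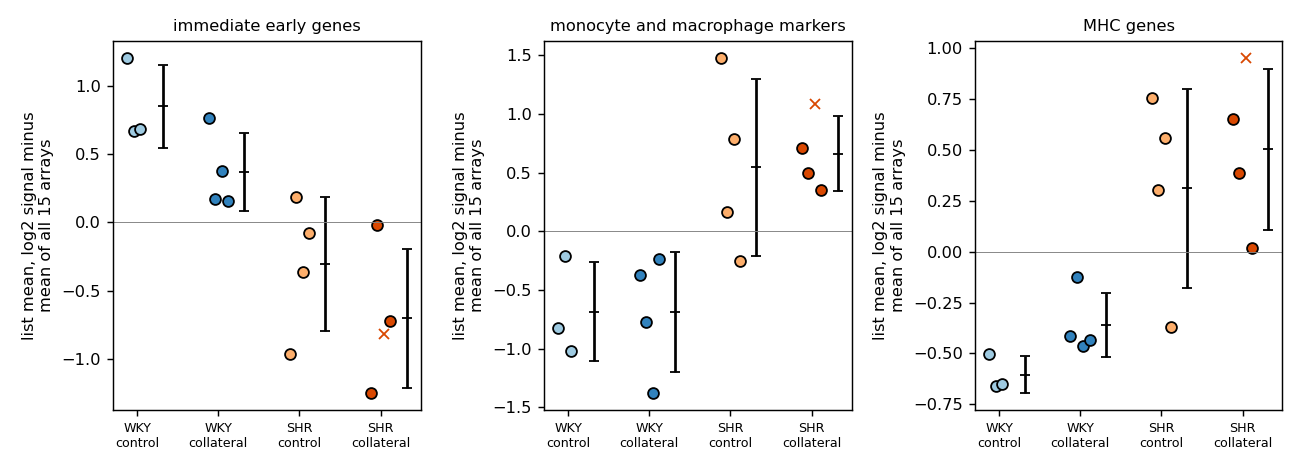
Mean of each gene list on each array, as log2 signal minus the mean of all 15 arrays, with the mean and SD of each group at its right. The cross marks SHR collateral 3. Averaged over vessel types, SHR minus WKY was -1.11 for immediate early genes, 1.29 for monocyte and macrophage markers and 0.89 for MHC genes.

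The strain differences in the 2 vessel types, measured on separate arrays, had a Pearson correlation of 0.352 and a Spearman correlation of 0.282 across 6512 probe sets. At an unadjusted p under 0.05 in both, 71 were higher in SHR (9.70 expected for independent lists), 71 lower (6.46 expected) and 1 opposite. The mean of each list per array was then compared between strains by exact permutation of strain labels within vessel type, two-sided, a test added after seeing the data. Over both vessel types the difference was -1.11 for immediate early genes (exact p = 0.000408, the smallest that 2450 permutations can give, adjusted p = 0.0159 over 39 lists). It was 1.29 for monocyte and macrophage markers and 0.89 for MHC genes, each with an exact p of 0.00122 and an adjusted p of 0.0159. This permutation and the expected counts treat control and collateral arrays as separate samples. The labels do not say whether 1 animal gave both vessel types, and if so these p-values could be too small. Within 1 vessel type alone the exact p cannot go below 0.0286, and 0 lists passed after adjustment.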

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

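All tests of explanations in this part were chosen after the list shifts and the correlations of SHR collateral 3 were seen. For endothelial cells, MHC sequence, white cells, the 3' to 5' ratio as a covariate of the macrophage list, and the spike-in signal and 3' to 5' ratio of SHR collateral 3, the values tested or values close to them had been seen as well.

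Immediate early genes were lower in SHR in both vessel types, with a strain difference of the list mean of -1.11 (95% interval -1.56 to -0.65, model with vessel type). With spike-in signal as a covariate the difference was -1.10 (-1.58 to -0.61), and with the 3' to 5' ratio it was -1.23 (-1.86 to -0.59). As far as these measures read them, this argues against degradation as the whole cause, and weakly against labelling yield. The spike-in log2 signal was 17.40 on SHR collateral 3, against 13.35 to 15.79 on the others, so that covariate rests in large part on that array. Endothelial markers without Icam2 differed by -0.28 (-0.68 to 0.11). This interval holds 0 but also reaches -0.68, a large part of -1.11, so it cannot tell whether fewer endothelial cells had a share. The list also leaves out the called Icam2. A strain difference in the artery is a candidate explanation that was not tested apart from time to dissection or processing day, which the labels do not give.

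Monocyte, macrophage and MHC genes were higher in SHR, with a difference of 1.29 (95% interval 0.71 to 1.87) for the macrophage list. With the spike-in covariate it was 1.30 (0.68 to 1.92) and with the 3' to 5' ratio, which itself differed between strains, it was 0.99 (0.22 to 1.75), against labelling yield or degradation as the whole cause, while a part from degradation stays open. Macrophage markers outside the MHC list differed by 1.05 (0.55 to 1.54), which argues against MHC sequence differences as the whole cause, though not for the RT1 genes themselves. Lymphocyte markers differed by 0.28 (-0.26 to 0.81) and neutrophil markers by 0.41 (-0.70 to 1.52), so white cells of all kinds cannot be told apart from macrophages here because these intervals are wide. The macrophage list mean was uneven, at 1.47, 0.16, 0.79 and -0.25 on SHR control 1 to 4. Adipocyte markers stood at 1.11, 0.08, 0.88 and -1.01 on the same arrays. Over both vessel types the adipocyte strain difference was 0.46 (exact permutation p = 0.204). More macrophages in or around the SHR artery wall may account for the shift, and were not counted.

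SHR collateral 3 had a median Spearman correlation of 0.590 with the other arrays, against 0.828 to 0.869 in the rest of its group. Its spike-in signal was 3.05 times the highest of the other 14, as little labelled sample RNA would give. Its mean log2 3' to 5' ratio of 1.86 lay within the range of the others, so this ratio gave no sign of stronger degradation. With the low signals of this array raised, the ratio may read degradation poorly, so it does not exclude it. Over 142 probe sets that differed between strains in both vessel types without this array, it stood at 0.64 on a scale from -0.50 for WKY to 0.50 for the other SHR collaterals, against a WKY sample under an SHR label. Its list means were the highest of all arrays for many lists. Among these were neutrophil (2.10), lymphocyte (1.39), exocrine pancreas (1.37), skeletal and cardiac muscle (1.06) and mesothelial and epithelial markers (1.04). Renin-angiotensin (0.99), endothelin and prostanoid (0.98) and cytokine genes (0.70) were others. Its means were the lowest for contractile smooth muscle (-1.38), heat shock (-0.87), proteasome (-0.73) and cytosolic ribosomal genes (-0.51), among others. Low signals were raised on this array, so these means do not show which cells it held. No biological explanation of these values was tested.

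Other values stood far from the 3 others of their group, with 17 of 288 groups doing so where chance gives 14.4. The median signal of SHR control 4 was 322.9, against 292.1 to 296.7. The MHC list mean of WKY collateral 2 was -0.12, against -0.46 to -0.42. Oxidative phosphorylation stood at -0.0713 in SHR control 1 (others 0.10 to 0.13) and at -0.42 in SHR collateral 3 (others -0.03 to 0.04). SHR collateral 3 was also low for Fn1, at 12.73 against 14.17 to 14.41, and for Myh11, at 12.08 against 14.84 to 15.27. SHR collateral 4 was low for Fdps at 9.86 and Icam1 at 10.996, SHR collateral 2 low for C1qb at 9.06 and SHR collateral 1 high for Cdk1 at 9.48. WKY collateral 3 was low for Plaur at 9.61 and Cdk1 at 5.74 and high for Cpa3 at 7.92. SHR control 1 was low for Sult1a1 at 10.02, SHR control 2 high for Ptprj at 6.84, and SHR control 4 high for Spp1 at 12.29, all log2 signals.

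The collateral change differed between strains, by the test of the difference, for cholesterol synthesis (median -0.69) and cytosolic ribosomal proteins (median -0.24). Both calls were lost with an estimated correlation (adjusted p = 0.410 and 0.880) and with array weights (both 0.206). The first was also lost with a 60th percentile filter (0.156), and the second with quantile normalization (0.706) and without SHR collateral 3 (0.473) or WKY collateral 4 (0.0974).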

How the results depend on the processing

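Array weights without SHR collateral 3 were chosen after seeing the data. In every setting run, 0 probe sets passed for WKY, for SHR, for their difference and for their mean. The 2 calls between strains in control arteries became 0 with no filter, a 60th percentile filter or Welch's test, 1 without a variance trend, 7 with only the arrays of the 2 groups, 14 with array weights (8 higher, 6 lower) and 9 with array weights and no SHR collateral 3. The 0 calls between strains in collaterals became 6 at 0.10, 2 with only the 2 groups' arrays, 26 with array weights (7 higher, 19 lower) and 66 with array weights and no SHR collateral 3. With all arrays, the weights of SHR collateral 1 to 4 were 2.78, 0.67, 0.16 and 0.65, so the weighted SHR collateral mean rests mostly on SHR collateral 1. Leaving out SHR collateral 3 without weights gave 0 calls in collaterals. For these changes the cause was not tested. Left-out arrays gave 0 to 6 calls between strains in control arteries and 0 to 7 in collaterals, and 0 to 0 in the 4 other comparisons. The correlation of the collateral changes ranged from 0.0293 without WKY control 1 to 0.178 without SHR collateral 3.

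Lists called fell to 0 in all 6 comparisons with an estimated correlation and with fry. Fry's mixed form, for change in either direction, called 4 lists between strains in control arteries (immediate early, MHC, endothelial, adhesion and NF-kB), 4 in collaterals (the first 3 and angiogenic factors) and 0 in the 4 other comparisons. In WKY the 2 lists became 5 with no filter, 7 with the 60th percentile filter, 5 with only 2 groups and 4 with the mean of a gene's probe sets. In SHR the 10 became 0 with quantile normalization, 6 with equal medians, 3 with the 60th percentile filter, 5 without trend, 2 with array weights, 1 with array weights and no SHR collateral 3, and 2 with the mean of a gene's probe sets. For the difference, the 2 became 1 with quantile normalization or the 60th percentile filter and 0 with array weights, with or without SHR collateral 3. For the mean of strains, the 6 became 3 with quantile normalization. Left-out arrays gave 2 to 6 lists in WKY, 3 to 10 in SHR, 1 to 3 for the difference, 5 to 9 and 4 to 7 between strains in control and collateral arteries, and 5 to 9 for the mean. In SHR, the ribosomal median became -0.014 with camera upward (quantile normalization) and the contractile median, -0.599 to 0.0716 over left-out arrays, was highest without SHR collateral 3, where camera turned upward. The cause was not tested.

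With the replicate number as a fixed replicate block, 5 lists were called in WKY and 1 for the difference, 0 probe sets passed, and WKY collateral 4 had no partner. A random block (consensus correlation 0.0945) kept every count within 1.5 times. Only 2 of 7 same-numbered pairs had correlated deviations over 0.1 (0.31 for WKY 1 and 0.17 for WKY 3). Among 4 candidate partners each, 4 of 7 control arrays correlated best with their own number, more than chance gives on average. So few pairs cannot tell whether the numbers pair samples, and the main tests did not pair them.

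Setting array medians equal moved the median log2 difference of all probe sets from 0.06 to -0.12 in SHR, from 0.03 to -0.17 for the difference and from 0.12 to -0.12 between strains in collaterals. Over all settings the called lists kept their call in 708 cases, lost it in 226 and reversed in 2. Many of these settings left out an array outside the 2 groups compared, which leaves a list's log2 changes as they were. The 708 kept cases therefore say little about stability, and every call was lost with an estimated correlation and with fry. Named genes kept their side of the threshold in 6289 of 6469 cases, gained a call in 45 (30 with array weights), lost one in 26, and changed sign without a call in 109. Only Icam2 and Ptprj in control arteries had a call to lose, so all 26 losses were theirs. Of 15 fits that left out an array, Icam2 lost its call in 10 and Ptprj in 11. The other named genes had no call to lose, so the 6289 kept cases say little about stability. Dim probe sets limit what can be seen, since signal over background is low there.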

Other observations

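The tests of neutrophil and chemokine lists and the permutations without SHR collateral 3 in this part were chosen after the values were seen, while the counts over other splits of the samples were planned before they were run. In WKY, the list mean of neutrophil markers had a difference of 0.89, collateral minus control arteries (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.371). In SHR the difference was 0.30 (exact permutation p = 0.80), and it turned to -0.30 without SHR collateral 3 (exact permutation p = 0.743). White cells entering the collateral wall may raise them, but over both strains the exact permutation p was 0.240 for neutrophil markers and 0.250 for cytokines and chemokines, so these arrays do not settle it. Genes of the unfolded protein response had a median log2 change of 0.27 in WKY collaterals (camera, adjusted p = 0.0571, and 0.715 with an estimated correlation) and of 0.18 in SHR (adjusted p = 0.553). Camera called the list upward under 13 of 29 alternatives in WKY (adjusted p = 0.0172 to 0.0478) and 11 of 28 for the mean of strains (0.00266 to 0.0475), none of them with an estimated correlation or fry. For the mean of strains, camera also called cell cycle genes upward under 12 of 28 (adjusted p = 0.00331 to 0.0494). It called cholesterol synthesis upward under 6 of 28 (adjusted p = 0.00815 to 0.0319). For the unfolded protein response, the SHR median without SHR collateral 3 was 0.28 (camera, adjusted p = 0.0301), with an exact permutation p of 0.171 for the list mean. Over both strains exact permutation gave the unfolded protein response an adjusted p of 0.284. Between strains, the list mean of mast cell markers had a difference of 0.60, SHR minus WKY (95% interval 0.09 to 1.10), and that of erythroid markers one of 0.13 (-0.33 to 0.60). Neither passed exact permutation over both vessel types (adjusted p = 0.108 and 0.788).

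Chance could not be excluded for any count by splitting the same samples in other ways, where the real split counts as 1 of the splits in each tally. For the 2 calls in control arteries between strains, 2 of 35 splits gave as many, the real one and 1 other, which gave 7. For probe sets at an unadjusted p under 0.05 in that comparison, the real split gave 421, 4 of 35 splits gave as many and the highest other gave 518. In collaterals between strains, 10 of 35 splits gave as many as the real 496, with 1618 the highest other. A count several times the real one points to a structure of the samples, whose source was not tested. For collateral against control arteries, 9 of 35 splits gave as many as 206 in WKY (highest other 484) and 28 of 35 as many as 245 in SHR (highest other 958). For the difference, 93 of 100 drawn splits gave as many as 124 (highest other 1230), and for the mean, 31 of 100 gave as many as 333 (highest other 1372).

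Counts of called lists behaved alike. As many as the real number came from 25 of 35 splits in WKY (2 lists, highest other 8), 6 of 35 in SHR (10 lists, highest other 16) and 82 of 100 for the difference (2 lists, highest other 14). Between strains it was 12 of 35 in control arteries (7 lists, highest other 12) and 17 of 35 in collaterals (6 lists, highest other 9), and for the mean of strains 32 of 100 (6 lists, highest other 13). The number of called lists alone therefore does not set a comparison apart from other groupings of these arrays.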
